A study of Mus musculus with 16 samples.

How the data were processed

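Tumours derived from the KPC mouse were taken at sacrifice, per the labels, and measured as 16 libraries of 3′ RNA sequencing, 4 for each of control, immunotherapy, RFA and RFA plus immunotherapy. The labels' shared protocol names RFA at 15 W for 10 s, gemcitabine at 100 mg/kg and an immune checkpoint inhibitor at 5 mg/kg. No group is labelled with gemcitabine, and the target of the inhibitor is not named. RNA was extracted with Trizol and the miRNeasy kit, and libraries of polyA RNA were made with the QuantSeq 3′ kit, per the labels' protocols. Which of an animal's tumours was sampled and how long after treatment are not given in the sources used here. The labels do not state whether each library comes from a separate animal, so the p-values measure only the spread between these samples.

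The deposited values are RSEM expected counts per gene, per the file headers, with no scaling for depth. The submitters' processing notes name cutadapt 1.15, RSEM 1.3.1 and the genome build GRCm38 (mm10). The aligner, the annotation release and the strand setting are not given in the sources used here. The files hold 47069 genes, of which 46488 (98.8%) matched a symbol and position in GENCODE M21 (GRCm38). Between 33.2% and 84.6% of a library's counts lay in genes whose expected count was not whole (tolerance 0.005), that is, in genes that share reads with others. Total counts ranged from 3221587 to 5780186 per library. A floor of 3 counts, the upper limit that a count of 0 allows, came to 0.402 to 2.85 CPM. Reads without molecular identifiers are not independent molecules, so such floors cover counting error only.

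Expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 (12298 genes), scaled by TMM and fitted in 1 quasi-likelihood model with a mean for each of the 4 groups (12 residual degrees of freedom, biological coefficient of variation 0.450). The 5 contrasts of 2 groups and the interaction of both treatments were tested with the two-sided quasi-likelihood F test, at a Benjamini-Hochberg adjusted p under 0.05 over all genes. The SE of a log2 change is its size divided by the square root of F. CPM values are scaled by the TMM factors. All 44 gene lists (768 members, 765 of them in the files) were written before the data were examined, as were the main test and the alternatives unless stated otherwise; 43 had at least 3 tested members. They cover immune and stromal cell types, tissue that could be taken with the tumour, and signalling, stress and metabolic pathways. Members dropped by the filter on low counts were not tested, so counts and medians of a list's genes refer to its tested members. The filter asks for enough counts in any 4 libraries, so a weakly expressed gene can pass through a group where it is high. The count of members higher in that group is then partly selected. Lists were tested with camera of limma 3.58.1 on the edgeR fit, with the preset inter-gene correlation of 0.01 and with an estimated correlation, adjusted over the 43 lists of a comparison. The preset test was the more permissive in these data. Gene p-values adjusted over a list alone were adjusted within that list and not across the 43 lists, so some may pass by chance. List scores are the mean log2 CPM of a list with a prior count of 2, compared by exact two-sided permutation tests over the 70 arrangements of 4 against 4 libraries.

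Genes were named by a rule. For each pairwise comparison it took genes with an adjusted p under 0.05, a mean of at least 1 CPM and no overlap between the groups' libraries, up to 12 higher and 12 lower, passing over predicted genes and antigen receptor segments. It also took the members of smallest p in a list's direction, up to 4 from a list that moved with the preset correlation and up to 2 from others. Where fewer than 10 genes passed, it took the 10 of smallest p, as for the interaction, and it always took Pdcd1, Cd274, Ctla4, Cd8a, Cd4, Foxp3, Kras and Trp53. Predicted genes, pseudogenes and small nucleolar RNAs among the 10 of smallest p are left out of the text. Genes that overlap others, or have close paralogs, may take or lose reads of these.

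Alternatives were RLE factors, library totals alone, DESeq2 1.42.0, limma-voom with sample weights, no filter on low counts, a filter of 1 CPM in 4 libraries, the replicate number as a block, a fit of only the 2 groups compared, and leaving out each library. An acinar score as a covariate, leaving out 5 ribosomal RNA-like genes, and leaving out the 4 libraries of TMM factor under 0.8 were added after seeing the data, as were the list test of the interaction and the list scores. The test was checked on data simulated from the fit for the combination against control (12250 genes tested). It found 6%, 74%, 88% and 96% of 50 genes changed by a log2 of 1, 2, 3 and 4, and called 6 of 12011 unchanged genes. These changed genes were drawn from outside the gene lists and above an average log2 CPM of 1, so the shares do not cover weaker genes. Camera found both changed lists and called 0 of 37 unchanged ones. Each gene was simulated on its own, so this does not show how often correlated genes make camera call an unchanged list. In other splits of the real control and combination libraries, the preset test moved up to 25 lists. The splits with most lists kept 3 of the 4 libraries of each group together, so they held part of any real difference. Splits that put 2 libraries of each group on either side moved up to 17. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.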

Results

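The data are 3′ RNA sequencing of tumours derived from the KPC mouse model of pancreatic ductal adenocarcinoma, in which mutant Kras and Trp53 are switched on in the pancreas. The 16 libraries fell into 4 groups of 4: untreated control, immunotherapy (an immune checkpoint inhibitor, whose target the labels do not name), radiofrequency ablation (RFA, heating of tissue by an electrode), and RFA plus immunotherapy, called the combination below. The deposited counts came to 4137276, 5780186, 4102893 and 3777573 in control 1 to 4, and to 4448350, 3938289, 5725048 and 3221587 in immunotherapy 1 to 4. They came to 5276576, 4180024, 4020465 and 4118348 in RFA 1 to 4, and to 5457456, 4594894, 4187190 and 3900145 in the combination 1 to 4. Between 13433 and 17961 genes had a count in a library, and 12298 genes had enough counts to be tested.

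Libraries of one group differed in what their counts came from. The name ribosomal RNA-like stands here for 5 genes. CT010467.1 is annotated as ribosomal RNA, AY036118 and Gm42418 are non-coding genes that overlap it, and mt-Rnr1 and mt-Rnr2 are mitochondrial ribosomal RNA. Transcripts of these 5 genes took 16.1% to 30.9% of the counts in the combination and 27.7% to 44.8% in control. They took 81.2% in immunotherapy 4, where the non-coding gene AY036118 alone took 75.8%. Genes of pancreatic acinar cells, which make digestive enzymes, took 0.00427% to 0.00519% of the counts in control 1, 3 and 4 and 1.18% in control 2. Their share reached 6.52% in immunotherapy 1, 7.48% in RFA 2, 18.1% in RFA 4 and 3.42% in combination 1. The 4 libraries with a TMM scaling factor under 0.8 were immunotherapy 1 (0.775), immunotherapy 4 (0.328), RFA 2 (0.617) and RFA 4 (0.601). Pearson's r of log2 CPM (counts scaled to library size) between libraries of a group, across genes, ranged from 0.721 to 0.934; genes are not independent replicates.

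**Figure D1:**
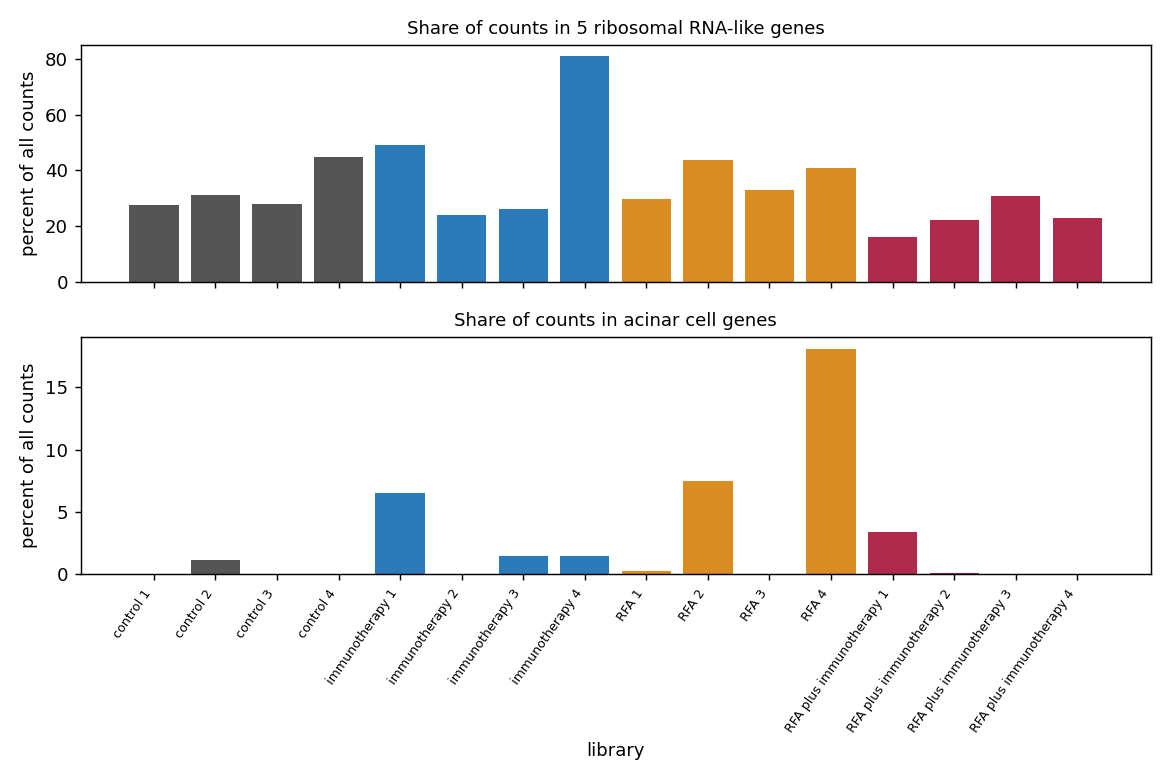
Share of each library's counts, in percent, taken by 5 ribosomal RNA-like genes and by the pancreatic acinar list, for the 16 libraries. The ribosomal RNA-like share was 81.2% in immunotherapy 4, and the acinar share was 18.1% in RFA 4 and 0.00427% in control 3.

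The first comparison asked how tumours given both treatments differed from untreated ones. S100a8 and S100a9, whose proteins form the calprotectin of neutrophils, rose in the combination by 4.65 ± 0.79 and 4.58 ± 0.70 on the log2 scale (SE, n = 4 per group, edgeR adjusted p = 0.0324 and 0.0196). S100a9 (ENSMUSG00000056071, GRCm38 chromosome 3, 90692632 to 90695721) averaged 6.25 ± 3.18 CPM in control and 147 ± 115 in the combination (SD, n = 4), and S100a8 (ENSMUSG00000056054, chromosome 3, 90668978 to 90670035) averaged 15.4 ± 6.93 and 383 ± 297. Socs1 (ENSMUSG00000038037, chromosome 16, 10782240 to 10785536), a cytokine-induced inhibitor of JAK and STAT signalling, rose by 1.92 ± 0.31 (adjusted p = 0.0299), from 5.91 ± 1.10 to 22.4 ± 4.29 CPM. Chil1 (ENSMUSG00000064246, chromosome 1, 134182176 to 134190181), a chitinase-like protein of macrophages and neutrophils, rose by 2.88 ± 0.50 (adjusted p = 0.0371). Igtp (ENSMUSG00000078853, chromosome 11, 58199556 to 58207591), an interferon-inducible GTPase, rose by 2.08 ± 0.31 (adjusted p = 0.0196), from 27.7 ± 6.81 to 117 ± 37.5 CPM. Igtp overlaps Irgm2 on the same strand and had fractional counts in 5 of 16 libraries, so its counts are partly uncertain. The related GTPase Tgtp2 (chromosome 11, 49057194 to 49064206) had 0 counts in all 4 controls and a mean of 49.95 ± 26.8 CPM in the combination, at least 353.5-fold higher than a floor of 3 counts over the control group (adjusted p = 0.0324). Tgtp2 is nearly identical to Tgtp1, so the split of reads between them is uncertain; their sum, chosen after the values were seen, was 31.7 ± 15.8 CPM in control and 108 ± 42.4 in the combination. For S100a8, S100a9, Socs1, Chil1, Igtp and Tgtp2, every combination library lay above every control library, which the rule for naming the genes with a small adjusted p asked for.

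These 6 genes, all higher, were the whole count from edgeR at an adjusted p under 0.05 out of 12298 tested; 1152 genes had an unadjusted p under 0.05 (558 higher, 594 lower), where chance alone gives 614.9. DESeq2 called 55 genes (45 higher, 10 lower) and limma-voom 69 (55 higher, 14 lower). All 6 were among the DESeq2 calls and 5 of them among those of limma-voom. With library totals edgeR called 3 genes, without a filter on low counts 37 (34 higher, 3 lower), and with only these 2 groups in the fit 95 (67 higher, 28 lower). The count fell to 0 without control 1, control 2, control 3, control 4 or combination 3, to 1 without combination 2, and to 4 without combination 1 or combination 4. Without the 4 libraries of low scaling factor it was 24 (22 higher), and with the acinar score of each library as a covariate it was 19.

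**Figure D2:**
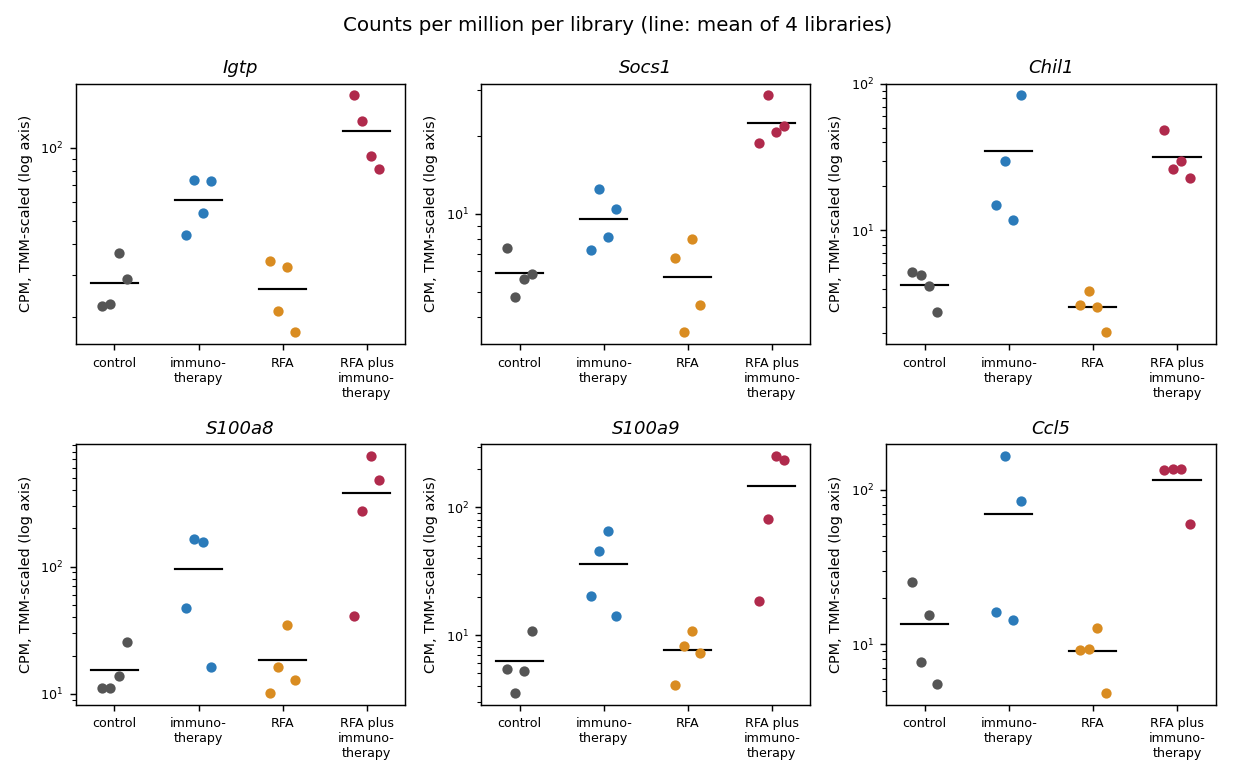
CPM per library, on a log scale, of 6 genes in each of the 16 libraries by group; points are libraries and lines the means of the 4 libraries. Socs1 averaged 5.91 CPM in control and 22.4 in the combination, and S100a9 averaged 6.25 and 147.

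Gene lists written before the data were examined moved in groups. Of 23 interferon-gamma response genes tested, 22 were higher in the combination than in control, with a median log2 change of 1.496. 3 of them rose over all genes and 15 when adjusted over the list alone (camera adjusted p = 1.87e-24, and adjusted p = 0.0240 with an estimated correlation). Cxcl10, which draws activated T cells, stood at 2.57 ± 0.47 (adjusted p = 0.0505) and Cxcl9 at 2.57 ± 0.58. Of 20 MHC class I presentation genes 18 were higher, with a median of 1.05; 0 rose over all genes with edgeR and 13 rose adjusted over the list alone (adjusted p = 0.0193 with an estimated correlation). Tap1, which carries peptides into the endoplasmic reticulum, stood at 2.12 ± 0.49, and the immunoproteasome subunits Psmb8 and Psmb9 at 1.75 ± 0.41 and 2.15 ± 0.51. H2-D1, a class I heavy chain with close paralogs and so a partly uncertain count, stood at 1.64 ± 0.38. The 20 type I interferon genes had a median of 1.11 and 7 rose adjusted over the list alone (adjusted p = 0.0240 with an estimated correlation), among them Zbp1, a sensor of nucleic acids, at 2.19 ± 0.50. Without control 2 the adjusted p with an estimated correlation was 0.0657 for the interferon-gamma and type I lists and 0.0507 for MHC class I. Without control 1 it was 0.0577 for both interferon lists, and without combination 1 it was 0.0514 for the type I list.

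All 8 tested genes of cytotoxic T and NK cells were higher, with a median of 2.66, and 6 rose adjusted over the list alone (adjusted p = 0.0193 with an estimated correlation). Ccl5, a chemokine of activated T cells, stood at 3.10 ± 0.66, Xcl1, which draws cross-presenting dendritic cells, at 3.26 ± 0.75, and Nkg7, a protein of cytotoxic granules, at 2.39 ± 0.56. All 14 tested genes of the 22 in the T cell list were higher, with a median of 1.82 and 8 up adjusted over the list alone (adjusted p = 0.0301 with an estimated correlation). In both lists the other members had too few counts to be tested. Weakly expressed members could pass the filter through the combination, so that all were higher may partly reflect the filter. Without the filter the calls of both lists with an estimated correlation were kept. Cd8a, the CD8 coreceptor, stood at 2.66 ± 0.67 and averaged 1.49 ± 1.19 CPM in control and 9.57 ± 5.57 in the combination. Of 16 neutrophil genes 15 were higher, with a median of 2.62 and 8 up adjusted over the list alone, 2 of them over all genes (adjusted p = 0.0240 with an estimated correlation); Camp and Ngp, granule proteins, stood at 5.15 ± 1.154 and 5.05 ± 1.14. Without control 3, Cd8a stood at 3.38 and Ngp at 6.58. Classically activated macrophage genes had a median of 1.64 (adjusted p = 0.0240 with an estimated correlation), with Nos2, the inducible nitric oxide synthase, at 2.57 ± 0.74; the median was 0.92 without combination 1 and 0.895 without combination 2. Checkpoint and exhaustion genes had a median of 0.92 (adjusted p = 0.0193 with an estimated correlation), with Pdcd1, the gene of PD-1, at 3.87 ± 0.72 (adjusted p = 0.0578) and Pdcd1lg2, which encodes a PD-1 ligand, at 1.92 ± 0.59. Inflammatory cytokines and chemokines had a median of 0.75 (adjusted p = 0.0427 with an estimated correlation). Without control 2 the adjusted p with an estimated correlation was 0.0507 for the cytotoxic and checkpoint lists, 0.0657 for T cells, neutrophils and classical macrophages and 0.0907 for inflammatory genes. Without control 1 it was 0.0577 for T cells, neutrophils and classical macrophages and 0.0866 for inflammatory genes, and without combination 1 it was 0.0514 for T cells and classical macrophages and 0.0779 for inflammatory genes. The inflammatory list also stood at 0.0503, 0.0550, 0.0559 and 0.0703 without control 3, control 4, combination 2 and combination 3. Some genes stand in more than 1 list, so the lists are not independent. The acinar share was 3.42% in combination 1 and 1.18% in control 2, and the ribosomal RNA-like share was 16.1% to 30.9% in the combination and 27.7% to 44.8% in control.

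The list of epithelial-mesenchymal transition genes fell, with a median of -0.55 and 3 of 14 members higher (adjusted p = 0.0434 with an estimated correlation). Its members Prrx1 and Twist1, transcription factors of mesenchymal cells, stood at -0.87 ± 0.28 and -1.03 ± 0.38, and Tnc, a matrix protein, at -0.88 ± 0.34; 0 members changed with edgeR over all genes or adjusted over the list alone. Without control 1, control 2, combination 1 or combination 4 the list's adjusted p with an estimated correlation was 0.0866, 0.0891, 0.0779 and 0.0740. For 20 genes induced by KRAS and ERK signalling the median was -0.40, with 3 higher and 3 down adjusted over the list alone (adjusted p = 0.0982 with an estimated correlation). Among these the EGF receptor ligand Ereg stood at -1.12 ± 0.32, and the ERK inhibitors Dusp4 and Spred1 at -1.02 ± 0.33 and -0.80 ± 0.26. Monocyte and macrophage genes had a median of 1.01 (adjusted p = 0.0723 with an estimated correlation) and MHC class II genes 1.21 (adjusted p = 0.0702 with an estimated correlation).

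Camera with its preset correlation moved 22 of 43 lists in this comparison (18 up, 4 down), and 10 held with an estimated correlation (9 up, 1 down). The 10 were the interferon-gamma, type I interferon, MHC class I, cytotoxic, T cell, neutrophil, classical macrophage, checkpoint, inflammatory and epithelial-mesenchymal transition lists. Without control 2 the count of 10 was 0, without control 1 it was 3, and without combination 1 it was 5. It was 8 without the 4 libraries of low scaling factor, 5 with only these 2 groups in the fit and 0 with library totals in place of TMM factors. As list scores (mean log2 CPM), interferon-gamma genes averaged 3.45 ± 0.44 in control and 5.10 ± 0.19 in the combination (SD, n = 4), with every combination library above every control (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 allows, and 0.0819 after Benjamini-Hochberg adjustment over the 43 lists).

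**Figure D3:**
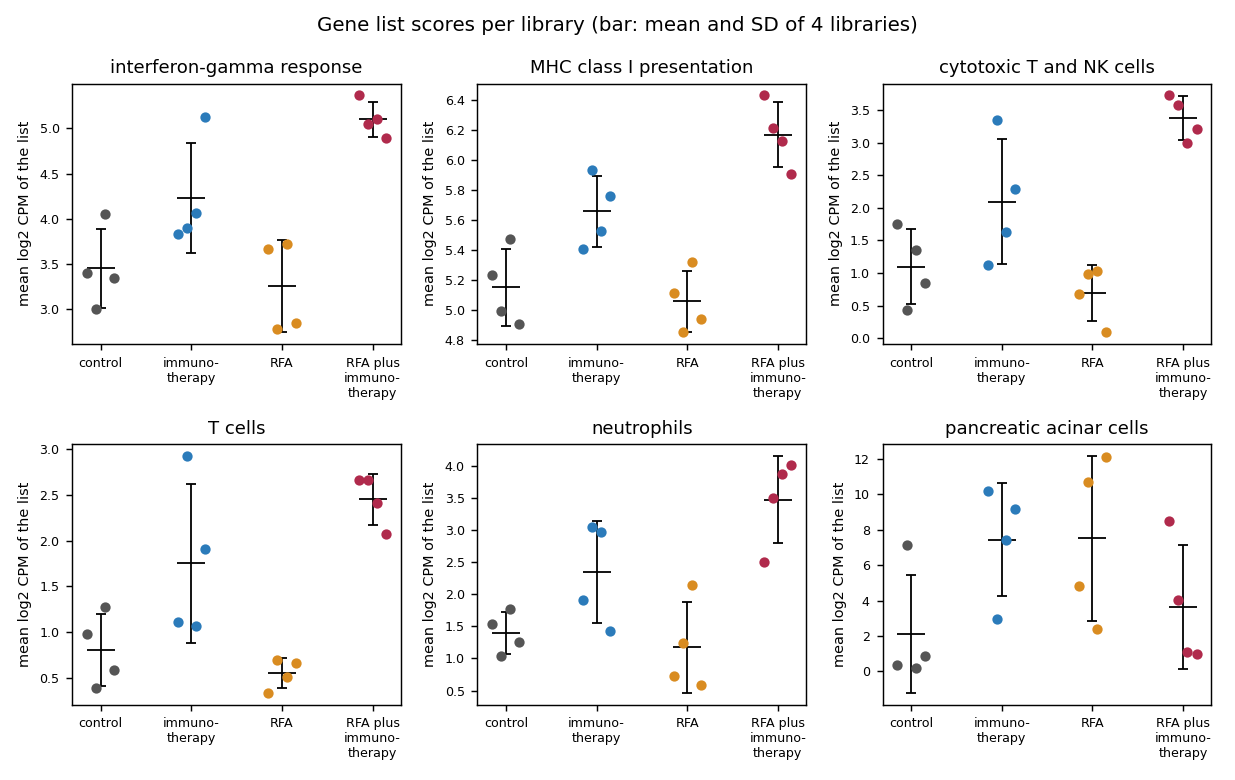
Mean log2 CPM of 6 gene lists in each of the 16 libraries by group; points are libraries, and bars the mean and SD of the 4 libraries. The interferon-gamma score averaged 3.45 in control, 4.23 in immunotherapy, 3.26 in RFA and 5.10 in the combination.

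The second comparison, the combination against RFA alone, asked what immunotherapy added to RFA. S100a9 and S100a8 rose by 4.28 ± 0.69 and 4.36 ± 0.78 on the log2 scale (SE, n = 4 per group, edgeR adjusted p = 0.0224 and 0.0318). Nkg7 (chromosome 7, 43437073 to 43438249) rose by 3.68 ± 0.63 (adjusted p = 0.0226) and Ccl5 (chromosome 11, 83525778 to 83530518) by 3.67 ± 0.69 (adjusted p = 0.0360). Cxcr6, a chemokine receptor of tissue-resident T cells, rose by 3.30 ± 0.65, Ltf, an iron-binding protein of neutrophil granules, by 3.43 ± 0.65, and Saa3, an acute-phase protein, by 3.34 ± 0.62. Chil1 rose by 3.39 ± 0.53, Socs1 by 1.94 ± 0.32, Cxcl10 by 2.42 ± 0.47 and Arg1, the arginase of myeloid cells, by 2.18 ± 0.37. Tap1 rose by 2.78 ± 0.51, Igtp by 2.14 ± 0.31, Ifi47, an interferon-inducible GTPase, by 1.84 ± 0.31 and the transcription factor Batf2 (chromosome 19, 6140983 to 6172476) by 2.98 ± 0.49. Tap1, Igtp, Ifi47 and Batf2 overlap other genes, so their counts are partly uncertain. The coagulation factor F7 rose by 2.63 ± 0.49 and AW112010, a transcript induced in activated immune cells, by 2.76 ± 0.50.

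These were all 17 genes from edgeR at an adjusted p under 0.05, all higher, with adjusted p from 0.0195 (Igtp) to 0.0497 (Cxcr6); 1582 genes had an unadjusted p under 0.05 (717 higher, 865 lower). DESeq2 called 121 genes (98 higher, 23 lower), the 17 among them, and limma-voom 18 (16 higher, 2 lower), with 9 of the 17. With library totals edgeR called 10 genes, with the replicate number as a block 7, without a filter on low counts 164 (97 higher, 67 lower) and with only these 2 groups in the fit 26 (24 higher, 2 lower). The count was 0 without RFA 2, 0 without RFA 4 and 62 without RFA 1, and it was 8, 3 and 1 without combination 1, 2 and 3. It was also 0 without the 4 libraries of low scaling factor, which leaves 2 RFA libraries, and 8 with the acinar score as a covariate. Without RFA 3, Nkg7 stood at 4.42 and Cxcr6 at 4.39. RFA 2 and RFA 4 had acinar shares of 7.48% and 18.1%.

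All 23 interferon-gamma genes were higher than in RFA, with a median of 1.76; 4 rose over all genes and 18 adjusted over the list alone (adjusted p = 0.0165 with an estimated correlation). The ribosomal RNA-like share was 29.7% to 43.9% in RFA and 16.1% to 30.9% in the combination. All 8 cytotoxic genes were higher, with a median of 3.00, 2 up over all genes and all 8 adjusted over the list alone (adjusted p = 0.0165 with an estimated correlation). The 14 tested T cell genes had a median of 2.32, all of them higher (adjusted p = 0.0309 with an estimated correlation). As against control, the filter may favour members that are higher in the combination. Trbc2, a T cell receptor constant gene, stood at 3.25 ± 0.68 and Cd3e at 3.54 ± 0.89 (without RFA 1, Cd3e had 1 count left in RFA). All 16 neutrophil genes were higher, with a median of 2.11, and 16 of 20 MHC class I genes, with a median of 1.23 and 14 up adjusted over the list alone (adjusted p = 0.0165 with an estimated correlation for both). Complement and coagulation genes had a median of 0.91, with 17 of 20 higher and 7 up adjusted over the list alone (adjusted p = 0.0165 with an estimated correlation), with coagulation factor F10 at 1.85 ± 0.44 and C3, the central complement protein, at 1.35 ± 0.44. The other lists that rose were checkpoints (median 0.81), inflammatory cytokines (0.99), danger signals of dying cells (0.39), classical macrophages (1.80) and type I interferon (1.22). Their adjusted p with an estimated correlation were 0.0165, 0.0238, 0.0238, 0.0309 and 0.0417. The checkpoint median was 1.46 without RFA 1, and that of classical macrophages was 1.2001, 0.84, 0.93 and 0.90 without RFA 3, RFA 4, combination 1 and combination 2. Without RFA 1 the adjusted p of all 11 lists with an estimated correlation lay between 0.0604 and 0.120. The T cell list stood at 0.0656 without RFA 3 and 0.0541 without combination 1, as did the inflammatory list at 0.0541 without the latter. Classical macrophages stood at 0.0548 without RFA 4 and 0.0697 without combination 1, and the type I list at 0.0690, 0.0565, 0.0852 and 0.0683 without RFA 3, RFA 4, combination 1 and combination 4. Of the danger signal genes, S100a8 and S100a9, also neutrophil genes, were the 2 that rose over all genes.

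Monocyte and macrophage genes had a median of 0.99, with all 20 higher (adjusted p = 0.0780 with an estimated correlation), and endoplasmic reticulum stress genes -0.44 (adjusted p = 0.258 with an estimated correlation), with Sel1l, a part of the machinery that degrades misfolded proteins, at -1.79 ± 0.54 (-0.74 without RFA 4) and the chaperone Hspa5 at -1.07 ± 0.36. The EGF receptor ligand Areg stood at -1.54 ± 0.39. The acinar list had a median of -3.94, with all 24 genes lower than in RFA (adjusted p = 0.414 with an estimated correlation); the median was -2.51 without RFA 4 and -8.11 without combination 1. Of the 22 lists moved with the preset correlation (18 up, 4 down), 11 held with an estimated correlation, all up. Without RFA 1 the count of 11 was 0, without combination 1 it was 7, and it was 0 without the 4 libraries of low scaling factor and with library totals in place of TMM factors.

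The third comparison, the combination against immunotherapy alone, asked what RFA added to immunotherapy. 0 genes changed with edgeR (516 with an unadjusted p under 0.05, 138 higher and 378 lower, fewer than the 614.9 that chance gives), 1 with DESeq2 and 0 with limma-voom; without a filter on low counts edgeR called 10 (2 higher). The genes of smallest p included Egr1, an early response transcription factor, at -1.23 ± 0.30, Socs1 at 1.23 ± 0.31, Ccl2, a chemokine for monocytes, at 1.58 ± 0.41, and Col7a1, a basement membrane collagen, at -1.76 ± 0.47 (SE, n = 4 per group, edgeR adjusted p = 0.972 each). When adjusted over the list alone, Egr1 (edgeR adjusted p = 0.00918), Socs1 (adjusted p = 0.0192) and Ccl2 (adjusted p = 0.0183) passed. Camera moved 21 lists with its preset correlation (16 up, 5 down) and 0 with an estimated one, the smallest adjusted p being 0.210. Interferon-gamma genes had a median of 0.73 with 21 of 23 higher (adjusted p = 0.257 with an estimated correlation), and monocyte and macrophage genes 0.57 with all 20 higher (adjusted p = 0.257 with an estimated correlation). The cytotoxic list had a median of 0.77 with all 8 higher, and the KRAS and ERK list -0.27 with 4 of 20 higher (adjusted p = 0.257 with an estimated correlation for both). Without immunotherapy 2 the cytotoxic median was 1.69. The acinar list had a median of -2.25 with all 24 lower (adjusted p = 0.348 with an estimated correlation), -1.29 without immunotherapy 1 and -6.54 without combination 1. Without immunotherapy 3 the preset count was 12. The ribosomal RNA-like share was 81.2% in immunotherapy 4, against at most 30.9% in the combination.

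The fourth comparison, RFA against control, asked what RFA alone left in the tumours. 0 genes changed with edgeR (618 with an unadjusted p under 0.05, 417 higher and 201 lower), 10 with DESeq2 (5 higher, 5 lower) and 0 with limma-voom; without a filter on low counts edgeR called 79 (65 higher). The genes of smallest p included Apln, a growth factor of new blood vessels, at -1.88 ± 0.37 (SE, n = 4 per group, edgeR adjusted p = 0.883), with 27.8 ± 11.9 CPM in control and 7.38 ± 2.06 after RFA. Cbs, an enzyme of sulfur amino acid metabolism, stood at 2.58 ± 0.57 (adjusted p = 0.954) and Crabp1, a retinoic acid binding protein, at -4.57 ± 1.13. Without RFA 4 Cbs stood at 1.79, and Crabp1 stood at -3.22 without control 1 and -5.20 without RFA 3. Cbs stood at 66.4 and 26.8 CPM in RFA 4 and RFA 2, the RFA libraries richest in acinar transcripts, and at 8.90 and 15.3 in RFA 1 and RFA 3. In control 2, the control richest in acinar transcripts, it stood at 3.95, within the control range of 3.80 to 6.12. Amd2 had 0 counts in all 4 RFA libraries, at least 21.6-fold lower than in control against a floor of 3 counts over the group. Without control 4 the bound was 16.4-fold. Amd2 was also at 0 in combination 1, combination 2, combination 3 and immunotherapy 4. All 24 acinar genes were higher, with a median of 5.52 and 4 up adjusted over the list alone (adjusted p = 0.2802 with an estimated correlation), among them the protease genes Ctrc at 6.89 ± 2.09 and Cela1 at 6.75 ± 2.13. In control, Ctrc had counts in control 2 alone. Without control 2 it was at least 466.2-fold higher in RFA against a floor of 3 counts over the 3 controls left, Cela1 stood at 8.83, and the acinar median was 11.2 with the 4 genes then at 0 in control set to such bounds. Without RFA 4 the acinar median was 4.11, Ctrc 4.31 and Cela1 4.27. Without the 4 libraries of low scaling factor, 2 of them RFA libraries rich in acinar transcripts, Ctrc had 0 counts in the 2 RFA libraries left, so its change is not given, and Cela1 stood at -0.62, with most of its control CPM in control 2. Endocrine islet genes had a median of 2.53 with 7 of 8 higher, endoplasmic reticulum stress genes 0.54 with 14 of 18 higher, and hypoxia genes -0.36 with 3 of 19 higher (adjusted p = 0.273 with an estimated correlation for each). The islet median was 1.93 without RFA 2. Asns, the asparagine synthetase, stood at 1.57 ± 0.44 and Bnip3, a hypoxia-induced mitophagy receptor, at -1.24 ± 0.35. Adipocyte genes had a median of -0.86 with 1 of 9 higher (adjusted p = 0.273 with an estimated correlation), -0.27 without control 3 and -1.62 without RFA 1. Adipoq, the gene of adiponectin, had 0 counts in all RFA libraries, at least 20.5-fold lower than the 3.66 ± 4.73 CPM of control; without control 3 the control mean was 1.34 CPM and the bound 7.47-fold. Camera moved 13 lists with its preset correlation (4 up, 9 down) and 0 with an estimated one. Without control 4 or RFA 2 the preset count was 8, it was 5 without the 4 libraries of low scaling factor, and it was 6 with the acinar score as a covariate.

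The fifth comparison, immunotherapy against control, asked what immunotherapy alone left in the tumours. 0 genes changed with edgeR (681 with an unadjusted p under 0.05, 379 higher and 302 lower), 2 with DESeq2, both higher, and 0 with limma-voom; without a filter on low counts edgeR called 11 (10 higher). Chil1 had the smallest p, at 2.95 ± 0.51 (SE, n = 4 per group, edgeR adjusted p = 0.203); without immunotherapy 3, 1 gene was called, and without immunotherapy 4 Chil1 stood at 2.08. The class I heavy chain H2-K1 stood at 1.93 ± 0.42, with 272 ± 63.3 CPM in control and 1035 ± 650 in immunotherapy (1995 in immunotherapy 4 and 552.6 to 796.7 in the others), Pdcd1 at 2.88 ± 0.74, S100a9 at 2.59 ± 0.65 and Igtp at 1.14 ± 0.30 (adjusted p = 0.878 each). When adjusted over the list alone, H2-K1 (edgeR adjusted p = 0.00415), Pdcd1 (adjusted p = 0.0116), S100a9 (adjusted p = 0.0134) and Igtp (adjusted p = 0.0140) passed. Interferon-gamma genes had a median of 0.77 with 22 of 23 higher and 6 up adjusted over the list alone, and MHC class I genes 0.74 with 17 of 20 higher and 2 up (adjusted p = 0.196 with an estimated correlation for both). Neutrophil genes had a median of 1.39 and T cell genes 1.49 (adjusted p = 0.196 with an estimated correlation for both). Immunotherapy 4 had a ribosomal RNA-like share of 81.2% and a scaling factor of 0.328; without it H2-K1 stood at 1.35, the interferon-gamma median at 0.26 and the MHC class I median at 0.39. The T cell median rested on immunotherapy 2 and was 0.45 without it. The acinar list had a median of 3.87 with all 24 higher (adjusted p = 0.265 with an estimated correlation), 9.46 without control 2 (with 4 genes at 0 in control set to bounds) and 2.87 without immunotherapy 1, and acinar shares were 6.52%, 1.49% and 1.496% in immunotherapy 1, 3 and 4. Camera moved 16 lists with its preset correlation (14 up, 2 down) and 0 with an estimated one; without immunotherapy 2 the preset count was 8.

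The interaction asked whether the effect of the combination differed from the sum of both treatments on the log2 scale. 0 genes passed with edgeR (935 with an unadjusted p under 0.05, 326 higher and 609 lower), 16 with DESeq2 (4 higher, 12 lower) and 0 with limma-voom; without a filter on low counts edgeR called 111 (15 higher). The genes of smallest p included Pid1, a regulator of insulin signalling, at 2.68 ± 0.55, and Col7a1 at -2.93 ± 0.65 (SE, n = 4 per group, edgeR adjusted p = 0.525 each); without control 2 Col7a1 stood at -3.52. Pid1 averaged 7.04 ± 2.93 CPM in control, 3.29 ± 0.909 in immunotherapy, 3.13 ± 0.915 in RFA and 9.53 ± 2.10 in the combination. Cbs stood at -3.40 ± 0.79 and Bnip3 at 2.07 ± 0.49 (edgeR adjusted p = 0.570 each, and 0.0088 for Bnip3 adjusted over the list alone; Cbs stood at -2.61 without RFA 4). The interferon-gamma list had a median of 0.91 (adjusted p = 0.486 with an estimated correlation), the cytotoxic list 1.25 (adjusted p = 0.397 with an estimated correlation) and the acinar list -7.74 (adjusted p = 0.342 with an estimated correlation). Without immunotherapy 2 the cytotoxic median was 2.26, and the acinar median was -13.7 without control 2 (over the 20 genes with counts in every group), -6.65 without immunotherapy 1, -6.39 without RFA 4 and -12.0 without combination 1. Of 13 lists moved with the preset correlation (11 up, 2 down), 0 held with an estimated one, so lists that held in one comparison and not in another were not shown to differ between them.

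**Figure D4:**
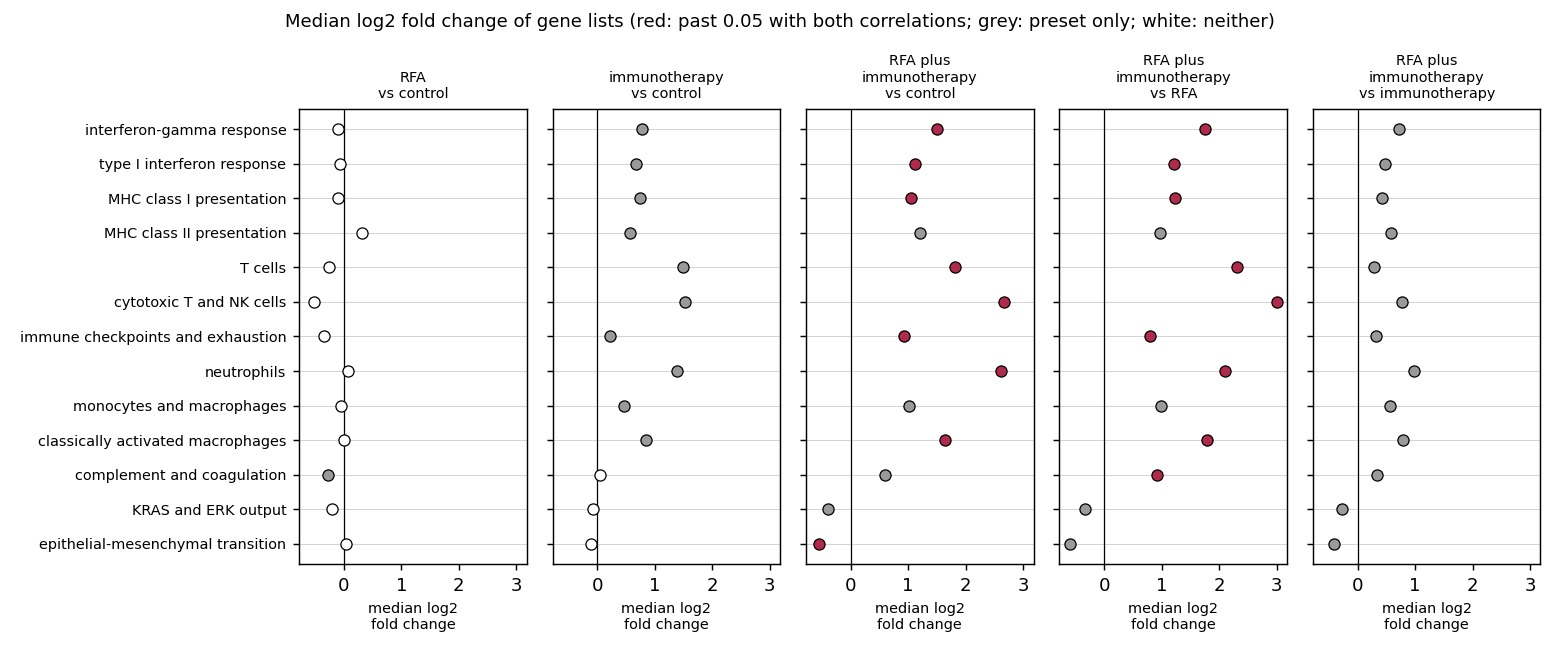
Median log2 fold change of 13 gene lists in 5 comparisons; red points passed camera with both correlations, grey points with the preset one alone and white points with neither. The interferon-gamma medians were 1.496 in the combination against control and 1.76 against RFA, both red, and 0.73 against immunotherapy, grey.

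Genes of the checkpoint and of the tumour model were read in every group. Pdcd1 averaged 0.261 ± 0.181 CPM in control, 2.18 ± 1.14 in immunotherapy, 0.490 ± 0.382 in RFA and 4.38 ± 1.92 in the combination (SD, n = 4). Cd274, the gene of PD-L1, averaged 3.91 ± 2.70, 4.91 ± 2.59, 3.37 ± 2.15 and 9.33 ± 1.73 CPM in the same order, and its change in the combination against control was 1.24 ± 0.50 (SE, edgeR adjusted p = 0.526), or 1.86 without control 3. Ctla4 had 0 counts in control and in RFA, 3 in immunotherapy and 5 in the combination, so a difference was not detectable at this depth. Cd4 averaged 0.406 ± 0.344, 1.71 ± 1.57, 0.318 ± 0.636 and 1.47 ± 0.758 CPM, and Foxp3, the regulator of regulatory T cells, 1.10 ± 0.878, 1.98 ± 2.37, 0.951 ± 0.852 and 1.34 ± 0.786. Among RFA libraries Cd4 had counts in RFA 1 alone. In immunotherapy 4, where a floor of 3 counts was 2.85 CPM, Cd4 stood at 3.79 and Foxp3 at 4.74 CPM. Foxp3 had 0 counts in immunotherapy 1 and immunotherapy 3, and its highest RFA value was 2.02 CPM in RFA 4. Kras averaged 112 ± 29.9, 71.9 ± 17.8, 88.4 ± 18.4 and 69.4 ± 11.2 CPM and Trp53 22.5 ± 13.6, 55.2 ± 27.2, 43.0 ± 12.5 and 26.9 ± 13.7.

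Effects of the treatments against the shared control group were compared across all 12298 genes, which are not independent replicates; calls could not overlap, since 0 genes passed with edgeR in RFA (618 with an unadjusted p under 0.05) and in immunotherapy (681) against control. The log2 changes of RFA and of immunotherapy had r = 0.693, against 0.477 in data simulated with no effect and a shared control, and 0.363 (0.308 to 0.410) when the 4 controls were split so that each effect had its own 2. Their covariance was 0.288, and 0.157 above the simulated one. The simulation drew each gene on its own and held no differences in sample content. The acinar score averaged 2.12 in control, 7.44 in immunotherapy and 7.52 in RFA. All 4 libraries of low scaling factor lay in immunotherapy and RFA. Neither the simulation nor the split controls therefore separate an effect shared by both treatments from uneven sample content. For RFA and the combination r was 0.277, against 0.497 simulated and 0.0147 (-0.132 to 0.170) with split controls, with a covariance of 0.106, which differed from the simulated one by -0.0254. For immunotherapy and the combination r was 0.502, against 0.482 simulated and 0.192 (0.0275 to 0.362) with split controls, with a covariance of 0.192, which was 0.0620 above the simulated one.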

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

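Tests chosen only after the result was seen were those of lymph node tissue, of acinar content behind the acinar list, of the share of tumour cells, of the interaction by lists and its splits, and the list scores with their acinar and ribosomal RNA-like covariates. The splits for lists with an estimated correlation were added after those counts were seen, but before the splits were run. In groups of 4 libraries, 118 in all over 30 measures, 9 had a library whose gap to the others exceeded Dixon's 95% critical value, where chance gives about 1 in 20 groups, here 5.9. RFA 1 stood apart in total counts, with 5276576 against 4020465 to 4180024 in the other RFA libraries. It also stood apart in Cd8a, at 2.09 as log2 of CPM plus 1 against 0.83 to 0.90, and in Cd4, at 1.18 against 0 in the others. Immunotherapy 2 stood apart in Kras, at 5.53 against 6.33 to 6.37, and immunotherapy 1 in Apln, at 3.15 against 4.07 to 4.25. Control 2 stood apart in its acinar share, 1.18% against 0.00427% to 0.00519%, in Ctrc, at 1.88 against 0, and in its acinar list score, 7.12 against 0.20 to 0.85. Combination 1 stood apart in its acinar share, 3.42% against 0.00769% to 0.116%.

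The interaction tests whether the effect of immunotherapy differed between tumours with and without RFA, and camera with its preset correlation marked 13 lists. Their medians were 0.85 for T cells, 1.25 for cytotoxic T and NK cells, 0.98 for neutrophils, 0.74 for monocytes and macrophages, 0.91 for interferon-gamma response, -7.74 for acinar cells and 1.146 for adipocytes. They were -0.69 for endoplasmic reticulum stress, 1.10 for danger signals of dying cells, 0.10 for hypoxia, 0.49 for glycolysis, 0.56 for complement and coagulation and 0.68 for mitochondrial transcripts. Without immunotherapy 2 those of T cells and cytotoxic cells were 1.80 and 2.26, and, over the genes with counts in every group, that of neutrophils was 1.34 without RFA 3, that of adipocytes 0.91 with all libraries and 0.68 without RFA 1, and that of acinar cells -13.7 without control 2. 0 of the 13 held with an estimated correlation, where the smallest adjusted p was 0.217.

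Interferon-gamma, MHC class I and cytotoxic genes were higher in the combination than in control. The interferon-gamma score, higher by 1.65 (SE 0.327), was higher by 1.71 (SE 0.330) with the acinar score as a covariate and by 1.74 (SE 0.365) with the log2 ribosomal RNA-like share, so neither is its whole cause. Lymph node tissue would raise B cell and lymph node stroma markers with the T cell list, but their summed CPM went from 45.2 to 21.1 while the T cell sum went from 34.4 to 121, and the rise of the former minus that of the latter was -2.57 (SE 0.663). Reads shared between class I paralogs were not tested, and the effect of both treatments, which the design names, stays among the open explanations. A candidate explanation is therefore a treatment-related change in immune cells or in their activity, which these libraries of whole tissue do not separate.

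The acinar list was higher in RFA and in immunotherapy than in control with the preset correlation (adjusted p = 0.2802 and adjusted p = 0.265 with an estimated correlation). Across the 16 libraries each acinar gene followed the mean of the other 23, with a median Pearson r of 0.991 and Spearman rho of 0.978 (permutation p = 1e-05 for both, the smallest that 100000 permutations can give), and r was 0.988 without RFA 4 and RFA 2. The score ranged over 6.92 inside the control group, more than the differences of 5.39 for RFA and 5.32 for immunotherapy, but over 0.65 without control 2. Inside RFA it ranged over 9.72 (8.30 without RFA 4) and inside immunotherapy over 7.22 (6.23 without immunotherapy 1). Uneven amounts of normal pancreas in the samples may account for the acinar differences, with support inside control from 1 library alone, and an effect of treatment on acinar tissue stays open.

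Genes of KRAS and ERK output were lower in the combination than in control, by -0.44 (SE 0.160) as a score, though the list test was lost with an estimated correlation. With the ribosomal RNA-like share as a covariate the difference was -0.37 (SE 0.176), lower by narrowly more than 2 SE. That margin is too small to decide whether the share is the whole cause. A lower share of tumour cells could lower these genes; the score of ductal and tumour epithelium genes, which would fall with it, differed by 0.52 (SE 0.540), too imprecise to decide. A treatment effect on this signalling stays open.

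Other splits of the same libraries into groups of 4 tell whether a count could arise by chance. For the combination against control, 1 of 35 splits, the real one, gave 6 genes (highest other 0), and against RFA 1 of 35 gave 17 genes (highest other 0). That is the smallest share these splits allow, and many counts were put to them. Chance is therefore less likely for both counts but not excluded. The 6 genes also fell to 0 without any 1 control, and the 17 to 0 without RFA 2 or RFA 4. The same limit holds for the lists with an estimated correlation. There 1 of 35 splits gave 10 against control (highest other 1) and 1 of 35 gave 11 against RFA (highest other 0). Where edgeR called 0 genes every split is as large by construction, so the splits say nothing about chance: 35 of 35 for RFA against control (highest other 24), immunotherapy against control (highest other 1) and the combination against immunotherapy (highest other 43), and 100 of 100 regroupings for the interaction (highest other 0). In these 4 comparisons the counts at an unadjusted p under 0.05 were 618, 681, 516 and 935, DESeq2 called 10, 2, 1 and 16, and limma-voom 0 in each. The split with 43 genes set immunotherapy 1, 3 and 4 and combination 1, the 4 libraries of highest acinar share among these 8, against the other 4, so it followed that structure of the samples. The split with 24 genes exchanged control 1 and RFA 1, and what it follows was not tested. For lists with the preset correlation, chance is not excluded for the 13 of RFA against control (6 of 35, highest other 15), the 16 of immunotherapy against control (4 of 35, highest other 20), the 22 of the combination against control (6 of 35, highest other 25), the 22 against RFA (3 of 35, highest other 24) or the 13 of the interaction (27 of 100 regroupings, highest other 23). Against control and against RFA, every other split of the combination with as many lists kept 3 of the 4 libraries of each group together. Such splits hold part of any real difference. Splits that put 2 libraries of each group on either side moved up to 17 lists against control and 10 against RFA. For the 21 of the combination against immunotherapy 1 of 35 splits, the real one, was as large (highest other 20). A margin of 1 list does not exclude chance for that count. That count was 12 without immunotherapy 3, and with an estimated correlation it was 0, where other splits gave up to 4.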

How the results depend on the processing

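The acinar covariate, the runs without ribosomal RNA-like genes and without the 4 libraries of TMM factor under 0.8, the list test of the interaction, and the estimated correlation together with other settings were tests chosen only after the result was seen. Of 2417 values of named genes under an alternative, 8 reversed in fitted sign, 3 of them with at most 3 counts in a group, 183 were no longer past the threshold and 158 newly passed it; of 2017 values of lists, 10 reversed, 1 of them in the direction of its test but not of its median, and 298 were no longer past it. All 10 lists that held with an estimated correlation in the combination against control, and all 11 against RFA, kept their preset calls under every setting run and without each library. The splits do not exclude chance for the preset counts. Calls with an estimated correlation were kept less often. For interferon-gamma the adjusted p with an estimated correlation ranged from 0.0135 to 0.0657 against control and from 0.0139 to 0.108 against RFA. Against control it reached 0.585 for epithelial-mesenchymal transition, kept in 3 of 9 settings and 4 of 8 fits without 1 library. It reached 0.450 for the inflammatory list, kept in 4 of 9 and 1 of 8. Against RFA it reached 0.525 for danger signals, kept in 6 of 9 and 7 of 8. The adjusted p of Igtp against control ranged from 2.43e-07 to 0.424. List tests were not run with DESeq2 or limma-voom, and a fit of only 2 groups gives no interaction. Except where fewer samples or genes enter, the cause was not tested.

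With an estimated correlation the lists moved were 0 for RFA and for immunotherapy against control, 10 (9 up) for the combination against control, 11 (all up) against RFA, and 0 against immunotherapy and for the interaction. With library totals the combination gave 3 genes against control and 10 against RFA, and 0 lists in both with an estimated correlation; this scaling moved the median log2 change of all genes to -0.33, -0.40, 0.10, 0.42, 0.51 and 0.85 (RFA, immunotherapy and the combination against control, the combination against RFA and against immunotherapy, interaction). In that same order DESeq2 called 10 (5 higher), 2 (both higher), 55 (45 higher), 121 (98 higher), 1 (lower) and 16 (4 higher) genes, and no filter on low counts gave 79 (65 higher), 11 (10 higher), 37 (34 higher), 164 (97 higher), 10 (2 higher) and 111 (15 higher). Limma-voom called 69 (55 higher) for the combination against control, where a fit of only the 2 groups called 95 (67 higher) genes and 5 lists with an estimated correlation; against RFA that fit called 26 (24 higher) genes and 7 such lists. The replicate number as a block gave 4 genes in the combination against control and 7 against RFA. Among 16 libraries, 5 correlated best with one of their own number, which gives no sign of pairing. What the numbers mark is not stated, so pairing is not excluded.

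With the acinar score as a covariate, the lists moved were 6 for RFA against control and 7 for the interaction, and the combination gave 19 genes against control and 8 against RFA. That setting reversed glycolysis in RFA against control (0.10) and in the interaction (-0.0407), Ctrc (-0.19) and Cela1 (-0.78) in RFA and Cela1 (-0.31) in immunotherapy against control, and neutrophils in the interaction (-0.23). It also turned the test direction of the acinar list in the combination against RFA, its median going from -3.94 to -0.0363. As this list makes the score, its genes, Ctrc and Cela1 included, shrink by construction. Without the 4 libraries of low scaling factor, lists moved in RFA against control were 5, and the combination gave 24 genes (22 higher) against control, 0 genes and 0 lists with an estimated correlation against RFA, where edgeR had 2 RFA libraries left. That setting reversed glycolysis (3.39e-04) and Cela1 (-0.62) in RFA against control, the acinar list (2.57) and Asns (0.16) in the combination against RFA, and oxidative phosphorylation (-0.0764), ribosomal proteins (-0.16) and mitochondrial transcripts (-0.0655) against immunotherapy. The fitted values of Ctrc (-5.16), Try10 (-1.74) and Bhlha15 (-1.07) in RFA against control turned as well. They rest on 0, 3 and 2 counts in RFA and on control 2 alone in control, so they are inexact and give no direction. Against a floor of 3 counts the bound for Ctrc was 2.61-fold.

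Leaving out 1 library at a time, genes called ranged from 0 to 0 in RFA against control, in the combination against immunotherapy and in the interaction, from 0 to 1 in immunotherapy against control (1 without immunotherapy 3), from 0 to 4 in the combination against control (0 without any 1 control or combination 3, 1 without combination 2), and from 0 to 62 against RFA (0 without RFA 2 or RFA 4, 1, 3 and 8 without combination 3, 2 and 1, 62 without RFA 1). Lists moved ranged from 8 (without control 4 or RFA 2) to 16 for RFA, from 8 (without immunotherapy 2) to 17 for immunotherapy and from 19 to 28 for the combination against control, from 19 to 25 for the combination against RFA, from 12 (without immunotherapy 3) to 22 against immunotherapy, and from 10 to 19 for the interaction. With an estimated correlation they ranged from 0 (without control 2; 3 without control 1 and 5 without combination 1) to 12 against control, and from 0 (without RFA 1; 7 without combination 1) to 11 against RFA. The acinar list in the combination against control ranged from -2.63 to 7.53 (1.40 with all libraries), reversed without combination 1, which held most of the group's acinar transcripts. With each effect given its own 2 controls, correlations across genes were 0.363 for RFA and immunotherapy, 0.0147 for RFA and the combination, and 0.192 for immunotherapy and the combination.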

Other observations

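The fat cell genes Adipoq and Cfd were singled out only after their values were seen, and no tests in this part were chosen after its results. Fat cell genes were unevenly present in the libraries. Adipoq averaged 3.66 ± 4.73 CPM in control (SD, n = 4), from 0.141 to 10.6 in single libraries, and 1.34 without control 3. Cfd, the gene of adipsin, which fat cells secrete, averaged 10.2 ± 12.8 CPM in control and had 0 counts in all 4 RFA libraries, at least 57.1-fold lower against a floor of 3 counts over the group. Cfd also had 0 counts in 1 control library, and without control 3 the control mean was 4.25 CPM and the bound 23.8-fold. Plasma cell genes also varied, with Jchain, which joins polymeric antibodies, at -2.17 ± 0.73 and Igkc, the kappa light chain, at -3.05 ± 1.07 on the log2 scale in RFA against control (SE, n = 4 per group). Without RFA 3 Jchain stood at -3.55 and Igkc at -5.25, and without control 3 Igkc stood at -2.38. The B and plasma cell list had 1 of 7 genes higher there (adjusted p = 0.273 with an estimated correlation), and its preset call was lost without RFA 1. Islet hormone genes Ins2 and Gcg stood at 3.55 ± 1.298 and 3.14 ± 1.12 in the same comparison (4.31 and 4.80 without control 2, and 2.40 for Gcg without RFA 4), beside acinar shares of 7.48% and 18.1% in RFA 2 and RFA 4.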
